A study of Rattus norvegicus with 21 samples.

How the data were processed

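Liver RNA of 21 male rats was profiled on an Affymetrix rat expression array with biotin-labelled RNA amplified from 100 ng of total RNA. The deposited values are log2 signals, 1 per probe set and array, summarised by RMA per the submitters' processing notes. The software, version and settings that ran RMA are not given in the sources used here. The values were used as deposited, with no further scaling, filter or pseudocount. All 21 value columns were matched to samples by title, and none had missing values. Array values carry no read depth, and the number of arrays, 3 per dosed group and 6 for the vehicle, limits precision.

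After exclusion of 57 array controls 31042 probe sets were tested. Of these, 20826 name 1 gene in the platform annotation, 436 several and 9780 none. Symbols were updated against the RefSeq gene table of assembly GRCr8, which served for names alone: 20758 through the Entrez identifier and 2 through an accession, while 66 kept the platform's symbol. A gene was represented by the probe set with the highest mean over all arrays among those naming that gene alone, which gave 14217 genes. Probe sets naming several genes were counted but not named. Cyp2b1, meant to be followed at every dose, has no probe set naming a single gene and is not analysed here. A further item of the plan is not reported here.

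Groups follow the dose in the labels. limma 3.58.1 in R 4.3.3 was used throughout (lmFit and eBayes, default variance settings). A single fit held all 21 arrays with a coefficient per group, so that the 6 groups shared the estimate of spread, and no covariate. Each dose was compared with the vehicle and each dose with the one below. A slope was fitted on the dose step (0 for the vehicle, then 1 to 5), and the moderated F covered the 5 dose coefficients. P-values are two-sided and adjusted by Benjamini-Hochberg over all probe sets tested within each comparison, with a threshold of 0.05. Standard errors are limma's moderated ones, and fold changes are 2 to the power of the log2 change. The expression "rose", "fell", "higher" or "lower" with a fold refers to a gene that passed this threshold at the dose named, unless an adjusted p above it is given.

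The gene lists, the tests, the groups, most alternatives and the rule for naming genes were fixed before the data were examined. The 34 lists held 636 members, 554 of them measured: CAR and PXR targets, phase II enzymes, drug transporters, aryl hydrocarbon receptor targets, Nrf2 targets, PPAR alpha targets, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, esterases, glucose handling, haem synthesis, urea cycle and amino acid catabolism, male-biased and female-biased genes, cell cycle, p53 targets, ER stress and ATF4 targets, heat shock proteins, acute phase, complement and coagulation, interferon response, glucocorticoid-responsive genes, clock genes, pericentral and periportal genes, and markers of hepatocytes, Kupffer cells, lymphocytes, neutrophils, stellate cells, endothelium, cholangiocytes and red cells. Some genes stand on several lists. Lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated per list, and with fry, whose p-value asks whether a list's genes move on balance in 1 direction. These p-values were adjusted over all lists and doses together. A list's count of members "adjusted over the list alone" uses only its own members in the adjustment at that dose.

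Genes were named by this rule: the 12 largest rises and 12 largest falls at 1032.5 mg/kg, and the 5 and 5 largest at every lower dose, among genes past the threshold whose 3 treated arrays all lay beyond all 6 vehicle arrays; the 5 and 5 largest differences between 1032.5 and 516.2 mg/kg, of which there were none; up to 4 called members of each list at 1032.5 mg/kg, or the 2 brightest where none was called; and index genes given whatever their values (Cyp3a23-3a1, Cyp1a1, Cyp4a1, Cyp7a1, Fasn, Nqo1, Ces2c, Alas1, Cyp2c11 and Abcc3). The rule named 121 genes. Where a group's mean lay below the lower quartile of the arrays, as for Acot1 in the vehicle group and Cdkn3 at 64.6 mg/kg, levels are given in place of a fold.

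The alternatives fixed beforehand were a fit with only the groups compared, cyclic loess, subtraction of each array's median, removal of the dimmer probe sets, 1 probe set per gene, an intensity trend with robust variance, array weights, a fold change of at least 1.5 as well, the replicate number as a block, other dose scales, fry, estimated correlations, lists without shared genes, the mean of a gene's probe sets, another probe set of a named gene, and each array left out in turn. Added after the data were seen were a covariate for the 5' minus 3' difference of the Gapdh and beta-actin controls, a slope among the 15 dosed arrays alone for probe sets and lists, a comparison of 1032.5 with 64.6 mg/kg, the vehicle arrays split 3 and 3 for the correlations, and the same alternatives for named genes other than the index genes. Correlations of fold changes were set beside 100 simulated pairs of unchanged groups and beside all 10 ways to split the vehicle arrays 3 and 3. Each simulated pair shared a simulated vehicle mean. The simulation drew independent noise for each gene with its residual SD and used no real vehicle array.

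The code was tested on simulated log2 values with known changes in 67, 67 and 66 of 31042 probe sets for folds of 1.5, 2 and 4. For 1032.5 mg/kg against the vehicle it called 76.1% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes, and 8 of 30842 unaltered probe sets. For 1032.5 against 516.2 mg/kg it called 61.2% of 1.5-fold and 94.0% of 2-fold changes. For the slope it called 86.6% of 1.5-fold and 98.5% of 2-fold changes over all arrays and 43.3% and 85.1% over the dosed arrays, and for the moderated F 64.2% and 95.5%. Over 14217 genes camera called the 1 list that had been shifted and 1 of 169 other list tests. The simulated noise was independent between probe sets, whereas the correlation estimated within lists of the real data reached 0.573. The simulation therefore does not show how often camera at the preset correlation calls unshifted lists in the real data.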

Results

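Liver expression was measured in male Harlan Sprague Dawley rats given tert-butylphenyl diphenyl phosphate (BPDP), a triaryl organophosphate ester used as a flame retardant and plasticiser. The compound was given by gavage in corn oil on 4 consecutive days, and pieces of the left liver lobe were taken on day 5. The series holds 21 arrays, labelled as replicates: 6 vehicle controls and 3 at each of 64.6, 129.2, 258.1, 516.2 and 1032.5 mg/kg, a range from 0.169 to 2.7 mmol/kg. The treatment protocol speaks of 5 vehicle rats, whereas 6 vehicle arrays are listed. All 6 were used as separate animals, which the labels leave unsettled. On every array 31042 probe sets were tested after 57 array controls had been set aside. Median log2 signal ranged from 6.32 at 516.2 mg/kg to 6.37 at 64.6 mg/kg over the group means. Pairs of arrays correlated at r between 0.984 and 0.995 across probe sets, which are not independent replicates, and no pair held identical values. Vehicle replicate 6 stood apart, with a mean r of 0.989 to its own group against 0.993 for the nearest of the other vehicle arrays. The difference between 5' and 3' control probe sets for Gapdh and beta-actin, a sign of RNA integrity, averaged -1.95 ± 0.29 (SD, n = 6) in the vehicle group, -2.30 ± 0.64 (n = 3) at 516.2 mg/kg and -1.54 ± 0.37 (n = 3) at 1032.5 mg/kg. The number of arrays limits the precision of every value that follows.

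The first question was how many transcripts each dose moved away from the vehicle. With limma and Benjamini-Hochberg adjustment, 77 probe sets changed at 64.6 mg/kg (42 higher, 35 lower), 108 at 129.2 mg/kg (69 higher, 39 lower), 731 at 258.1 mg/kg (423 higher, 308 lower), 1868 at 516.2 mg/kg (1247 higher, 621 lower) and 1908 at 1032.5 mg/kg (1024 higher, 884 lower). Among the 14217 genes represented by 1 probe set each, 55 were first called at 64.6 mg/kg, 44 at 129.2, 419 at 258.1, 882 at 516.2 and 550 at 1032.5 mg/kg, and 12267 were called at no dose. The share of genes whose 3 treated arrays all lay beyond all 6 vehicle arrays was 5.43%, 5.04%, 9.17%, 14.2% and 14.0% in order of dose, where chance gives 2.38%. The first principal component carried 21.7% of the variance and averaged -18.7 ± 6.20 (SD, n = 6) in the vehicle group, 21.4 ± 7.26 (n = 3) at 516.2 mg/kg and 19.8 ± 8.78 (n = 3) at 1032.5 mg/kg. The balance of directions depended on the scaling: at 516.2 mg/kg 1645 probe sets were higher and 421 lower with each array's median subtracted, and 992 higher and 712 lower with cyclic loess. At 64.6 mg/kg cyclic loess gave 44 higher and 46 lower.

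**Figure D1:**
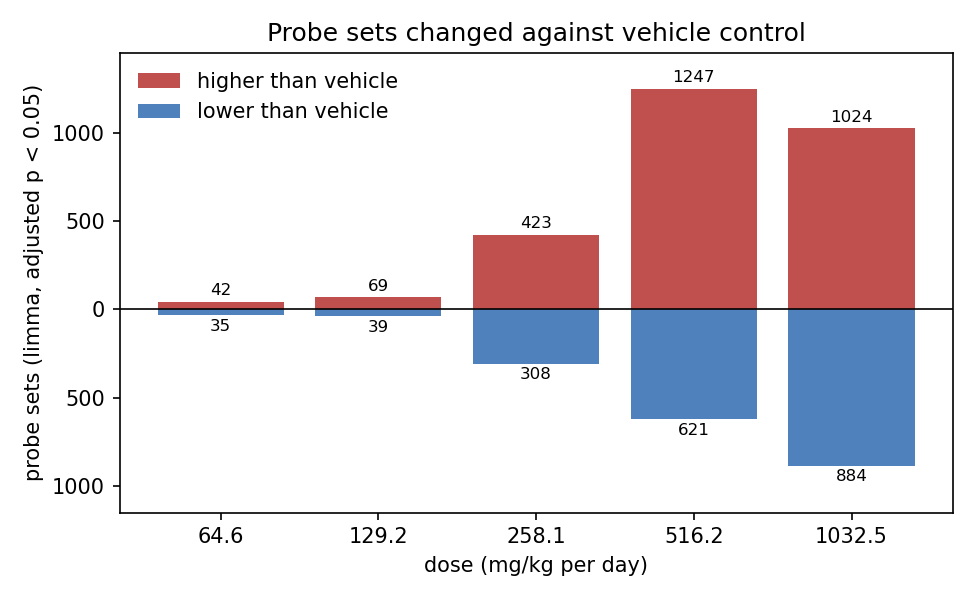
Number of probe sets higher (up) and lower (down) than in the 6 vehicle arrays at each dose in mg/kg, 3 arrays per dose, limma adjusted p under 0.05. The counts were 77 and 108 at the lowest doses and reached 1868 and 1908 at 516.2 and 1032.5 mg/kg.

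At 64.6 mg/kg the largest rises were in Dbp and Nr1d1 of the circadian clock, and Angptl4 and Cdkn1a were among the largest falls. Dbp, a transcription factor of the clock's output, rose from 5.78 ± 0.24 (SD, n = 6) to 10.21 ± 0.23 (n = 3) on the log2 scale, a 21.5-fold rise (log2 change 4.43, SE 0.23, adjusted p = 9.19e-10). Nr1d1, the repressor REV-ERB alpha, rose 7.02-fold (adjusted p = 2.74e-06) and Per3 5.25-fold (adjusted p = 3.76e-05), although the next probe set for Per3 did not pass at 1032.5 mg/kg (log2 change 0.14, adjusted p = 0.512). Bmal1, the core activator of the clock, was 3.81-fold lower (log2 change -1.93, SE 0.25, adjusted p = 0.000642), and Nfil3, which represses the targets of Dbp, was 3.53-fold lower (adjusted p = 6.36e-06). Of the 16 measured clock genes, 6 rose and 3 fell, or 9 and 5 adjusted over the list alone, and the list shifted upwards by camera (adjusted p = 1.51e-05, and adjusted p = 0.0553 with an estimated correlation). Outside the list, Hsd17b2, which oxidises oestradiol and testosterone, rose 5.52-fold and the deubiquitinase gene Usp2 4.02-fold. Angptl4, an inhibitor of lipoprotein lipase, was 4.32-fold lower (adjusted p = 0.00199), and Cdkn1a, which encodes the cell cycle inhibitor p21, was 4.18-fold lower (adjusted p = 3.97e-05). Hsd17b2, Usp2 and Cdkn1a were called at every dose, but limma called no slope among the 15 dosed arrays (adjusted p = 0.994, 0.294 and 0.759). For these genes an effect of the compound and a difference peculiar to the vehicle group cannot be told apart. Cdkn3, a cell cycle phosphatase gene, fell from a mean of 6.92 to 4.88 (adjusted p = 0.0397), a level too dim for an exact fold, and was the 1 of 29 measured cell cycle genes that passed. Leaving out replicate 1, 2 or 3 of this dose gave 49, 46 and 42 probe sets.

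At 129.2 mg/kg the largest rises were again in Dbp and Nr1d1, and the largest fall was in Scd. Dbp was 19.1-fold higher (log2 change 4.25, SE 0.23, adjusted p = 1.97e-09) and Nr1d1 6.62-fold higher, while Nfil3 was 3.65-fold lower and Lgalsl 3.21-fold lower. Of the clock genes, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.000559, and adjusted p = 0.0970 with an estimated correlation). Scd, which encodes the stearoyl-CoA desaturase, was 6.14-fold lower (adjusted p = 0.0349), and Pdk4, the kinase that switches off pyruvate dehydrogenase, was 3.09-fold lower (adjusted p = 0.00840). Zfp354a, a zinc finger gene, rose by 2.59 on the log2 scale (adjusted p = 0.00232). Abcc3, which exports conjugates across the basolateral membrane, was 2.87-fold higher (adjusted p = 0.0102), and Gsta3, a glutathione transferase, 2.36-fold higher (adjusted p = 0.00409). The count of 108 fell to 46, 34 and 44 without replicate 1, 2 or 3 of this dose, and to 71, 70 and 67 without vehicle replicate 1, 3 or 5.

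**Figure D2:**
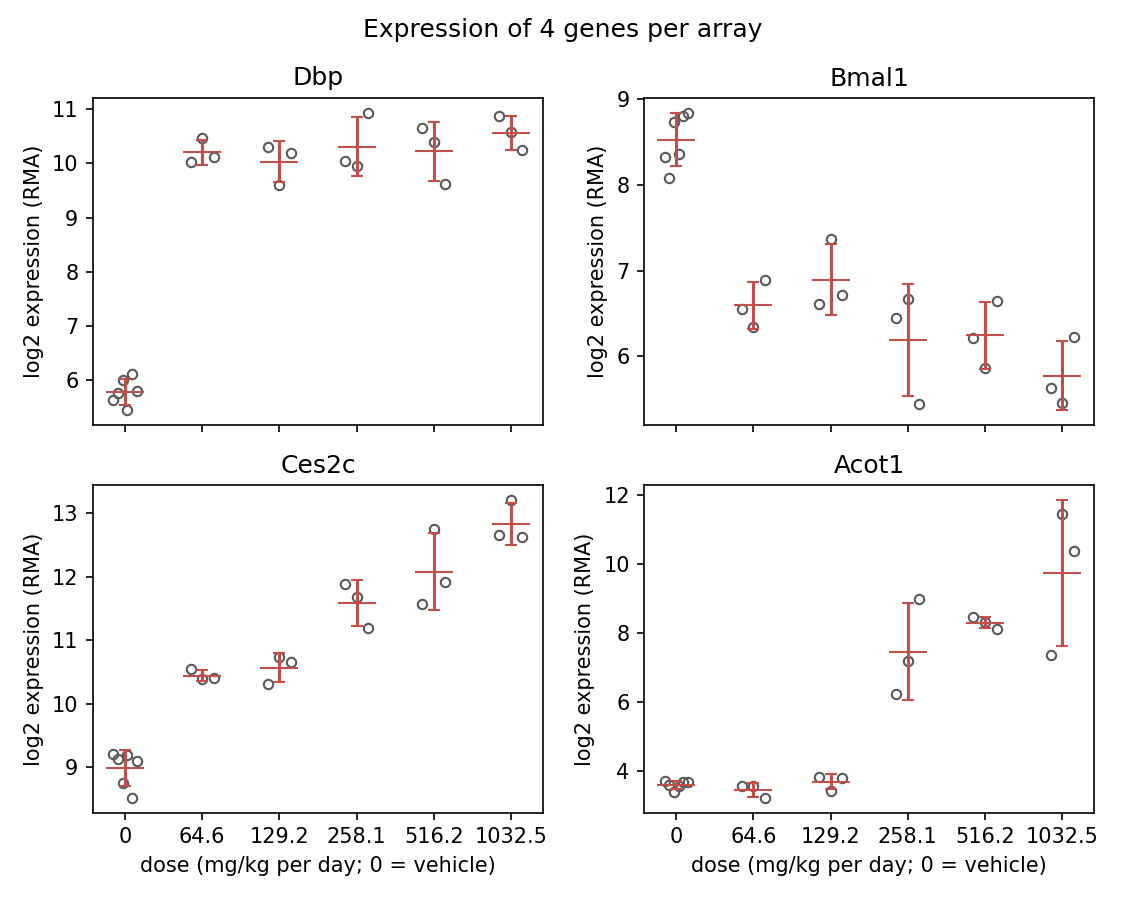
Log2 signal of Dbp, Bmal1, Ces2c and Acot1 on each array against dose in mg/kg (6 vehicle arrays, 3 per dose); points are arrays, and bars are the mean ± SD. Dbp and Bmal1 had moved by 4.43 and -1.93 at 64.6 mg/kg already, Ces2c climbed by 1.46 to 3.85 over the series, and Acot1 averaged 3.60 in the vehicle group and 7.46, 8.30 and 9.74 at the 3 highest doses.

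At 258.1 mg/kg some PPAR alpha targets rose and some genes of fatty acid synthesis fell. Acot1, an acyl-CoA thioesterase, averaged 3.60 ± 0.12 (SD, n = 6) in the vehicle group, 3.45 at 64.6 and 3.69 at 129.2 mg/kg, and rose here to 6.22, 7.18 and 8.98 on the 3 arrays (adjusted p = 0.000713). The vehicle level lies below the lower quartile of every array and was not shown to exceed background, so no fold is given for this gene. Ehhadh, the peroxisomal bifunctional enzyme, rose 3.15-fold, Vnn1, a pantetheinase, 3.04-fold and Cyp4a1, a fatty acid omega-hydroxylase, 2.29-fold. Of 34 measured targets of the fatty acid receptor PPAR alpha, 11 rose and 3 fell (19 and 4 adjusted over the list alone; camera adjusted p = 9.08e-08, and adjusted p = 0.291 with an estimated correlation). Of 21 genes of fatty acid synthesis, 1 rose and 5 fell, among them Scd (6.96-fold lower), Fasn, the fatty acid synthase (2.64-fold lower, adjusted p = 0.0269), and the liver pyruvate kinase gene Pklr (2.04-fold lower); adjusted over the list alone, 1 rose and 10 fell, and the camera adjusted p of 9.08e-08 became adjusted p = 0.193 with an estimated correlation. Of 21 cholesterol synthesis genes, 2 fell, or 10 adjusted over the list alone (camera adjusted p = 3.36e-08, and adjusted p = 0.295 with an estimated correlation). This list changed sign from dose to dose: its median log2 change was -0.16 at 64.6, 0.22 at 129.2, -0.47 at 258.1 and 0.17 at 516.2 mg/kg (camera adjusted p = 0.00901, 0.00242, 3.36e-08 and 0.380, and adjusted p of at least 0.295 with an estimated correlation). The taurine transporter gene Slc6a6 was 7.97-fold lower (SE of the log2 change 0.26, adjusted p = 1.38e-06) and the beta-tubulin gene Tubb2a 5.54-fold lower, and Ces2c, a carboxylesterase, was 6.07-fold higher. The count of 731 fell to 321 without replicate 1 of this dose and to 244 without replicate 3, and it was 474 with only the vehicle and 258.1 mg/kg arrays in the fit.

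At 516.2 mg/kg Acot1, Dbp and Ces2c were among the largest rises, and Slc6a6 and Scd had the largest falls. Acot1 averaged 8.30 ± 0.17 (SD, n = 3), Ces2c was 8.56-fold higher, Abcc3 7.06-fold and Gsta3 5.63-fold, and Slc6a6 was 12.1-fold lower. Of the PPAR alpha targets, 12 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 3.44e-06, and adjusted p = 0.344 with an estimated correlation). Asns and Psat1, which make asparagine and serine, reached their highest means of the series at 4.60-fold and 4.85-fold above the vehicle. Of 29 cell cycle genes, 8 rose and none fell, or 11 adjusted over the list alone (camera adjusted p = 3.66e-05, and adjusted p = 0.433 with an estimated correlation), whereas at 64.6 mg/kg none rose and 1 fell with the list shifted downwards (5 fell adjusted over the list alone; camera adjusted p = 1.69e-10, and adjusted p = 0.249 with an estimated correlation). Of 17 stellate cell and fibroblast markers, 7 fell, or 9 adjusted over the list alone, and Pdgfra was 1.74-fold lower (camera adjusted p = 2.72e-07, and adjusted p = 0.201 with an estimated correlation). Of other cell markers, none of 14 Kupffer cell, 3 of 14 endothelial and 1 of 17 lymphocyte markers fell, or 10, 6 and 1 adjusted over the list alone (camera adjusted p = 6.11e-06, 0.000170 and 0.00105, and adjusted p = 0.322, 0.347 and 0.297 with an estimated correlation). Of 28 genes of the urea cycle and amino acid catabolism, 2 rose and 6 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.00401, and adjusted p = 0.117 with an estimated correlation), with ornithine aminotransferase (Oat) 3.75-fold lower. The count of 1868 fell to 631 without replicate 1 of this dose and to 877 without replicate 3.

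At 1032.5 mg/kg Acot1 read 7.38, 11.46 and 10.37 on the 3 arrays against a vehicle mean of 3.60 (adjusted p = 1.34e-06). These 3 arrays were far apart (SD 2.11). The strongest of the other rises were in Dbp, at 27.6-fold (adjusted p = 2.11e-10), and Ces2c, at 14.4-fold (log2 change 3.85, SE 0.21, adjusted p = 1.32e-09). Zfp354a followed with a log2 change of 3.34 and Abcc3 with 3.17. Hdc, which makes histamine, had a log2 change of 3.04, the rhythmic gene Noct 2.78, Gsta3 2.76, Usp2 2.75, Hsd17b2 2.53 and the lipid droplet gene Cidea 2.42. The deepest falls were in Slc6a6 (15.2-fold lower, log2 change -3.92, SE 0.26, adjusted p = 1.42e-08), Npas2, a partner of Bmal1 (11.3-fold lower, adjusted p = 1.84e-07), and Scd (10.2-fold lower, adjusted p = 0.000455). The immediate early gene Egr1 was 7.08-fold lower, Rprm 6.77-fold, Bmal1 6.74-fold, Stac3 6.21-fold, Tubb2a 5.94-fold, Dhrs7l1 5.85-fold, Cdkn1a 4.98-fold and the phosphate transporter gene Slc34a2 4.86-fold. Each of these had an adjusted p of at most 0.00147 and all 3 treated arrays beyond all 6 vehicle arrays. The protease inhibitor gene A2m was 4.38-fold lower (adjusted p = 0.0441), a call lost without any of vehicle replicates 1, 3, 5 or 6 or of the 1032.5 mg/kg replicates (adjusted p from 0.0641 to 0.201), with only the compared groups in the fit (0.0881) or with the RNA integrity covariate (0.0740). Without replicate 2 of this dose the count of 1908 became 1136.

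Nrf2 targets and conjugating enzymes rose more often than they fell at 1032.5 mg/kg. Of 19 measured targets of the oxidant sensor Nrf2, 10 rose and none fell, or 14 adjusted over the list alone. Under camera this was the single list shift that held with an estimated correlation at any dose (adjusted p = 4.05e-11, and adjusted p = 0.0269 with that correlation). Akr7a3, an aldehyde reductase, was 4.73-fold higher (log2 change 2.24, SE 0.14, adjusted p = 6.13e-09), and Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, were 3.04-fold and 2.42-fold higher. Nqo1 was 1.70-fold higher (adjusted p = 0.00413) and Gsr 2.36-fold higher (adjusted p = 0.00757), calls lost without replicate 2 of this dose (adjusted p = 0.0507 and 0.0805). Of 22 phase II conjugation enzymes, 10 rose and 1 fell, or 11 and 2 adjusted over the list alone (camera adjusted p = 1.11e-07, and adjusted p = 0.0706 with an estimated correlation). Besides Gsta3 these included Gstt3, at 3.48-fold, and Ugt2b1, a glucuronosyltransferase, at 2.23-fold. Of 13 targets of the xenobiotic receptors CAR and PXR, 6 rose and none fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 6.11e-06, and adjusted p = 0.0970 with an estimated correlation). Their largest rises were in Por (2.73-fold), Aldh1a1 (2.72-fold) and Ephx1 (1.92-fold), and Cyp3a23-3a1 was 1.85-fold higher (log2 change 0.88, SE 0.14). Of 12 drug transporters, 4 rose and 2 fell, or 4 and 4 adjusted over the list alone. The list did not shift by camera (adjusted p = 0.313), but it passed by fry (adjusted p = 0.0418). Other lists that camera did not call at this dose also passed by fry. They were hepatocyte markers (fry adjusted p = 5.30e-05), urea cycle and amino acid genes (0.00812) and bile acid genes (0.0159). Neutrophil markers (0.0200) and periportal genes (0.0293) did as well. Abcb1a was 3.13-fold higher and the organic anion carrier gene Slc22a8 2.17-fold lower.

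Among 7 targets of the aryl hydrocarbon receptor, 2 rose and 1 fell, counts that held adjusted over the list alone, and the list did not shift (camera adjusted p = 0.812, with a median log2 change of -0.08 and a mean of 0.24). Its members went apart: Cyp1a1 was 5.02-fold higher (adjusted p = 4.82e-06) and Cyp1a2, the abundant hepatic member, 2.24-fold lower (adjusted p = 8.69e-07). Of 7 haem synthesis genes, 2 rose, or 2 with 3 falls adjusted over the list alone (camera adjusted p = 0.597). Alas1, the rate-limiting enzyme, was 3.66-fold higher (adjusted p = 0.000148), while the call of Uros was lost without replicate 1 of this dose (adjusted p = 0.122). Of 18 esterases, 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.940, with a median of -0.08 and a mean of 0.15). Ces2c led the rises, and hepatic lipase, Lipc, was 1.46-fold lower.

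PPAR alpha targets also rose more often than they fell at 1032.5 mg/kg. Of 34 PPAR alpha targets, 18 rose and 2 fell, or 24 and 2 adjusted over the list alone (camera adjusted p = 5.57e-16, and adjusted p = 0.116 with an estimated correlation). Aqp7, a glycerol channel gene, was 3.95-fold higher, Ehhadh 3.88-fold, Vnn1 3.49-fold and Cyp4a1 2.58-fold. Pdk4, also on this list, was 2.10-fold lower (adjusted p = 0.0230), a call lost without replicate 1 of this dose (adjusted p = 0.216) and with only the compared groups in the fit (adjusted p = 0.0784). Of 21 genes of fatty acid synthesis, 2 rose and 3 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0839). Me1, the malic enzyme gene, was 3.47-fold higher and Pklr 2.32-fold lower, whereas Fasn was at a log2 change of -0.15 (SE 0.33, adjusted p = 0.890). Of 21 cholesterol synthesis genes, 1 rose, or 1 with 1 fall adjusted over the list alone (camera adjusted p = 0.0955). It was Msmo1 (log2 change 0.75, adjusted p = 0.0448), a call lost without any of the 3 arrays of this dose (adjusted p = 0.209, 0.0665 and 0.120) or vehicle replicate 2, 4, 5 or 6, and with only the compared groups (0.109), cyclic loess (0.0523) or the RNA integrity covariate (0.0841). Of 20 genes of bile acid synthesis and transport, 1 rose and 5 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.113). Nr0b2, the repressor SHP, was 3.72-fold higher, the sterol exporter gene Abcg8 2.70-fold lower and the bile acid CoA ligase gene Slc27a5 1.76-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 change of 0.23 (SE 0.40, adjusted p = 0.844).

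**Figure D3:**
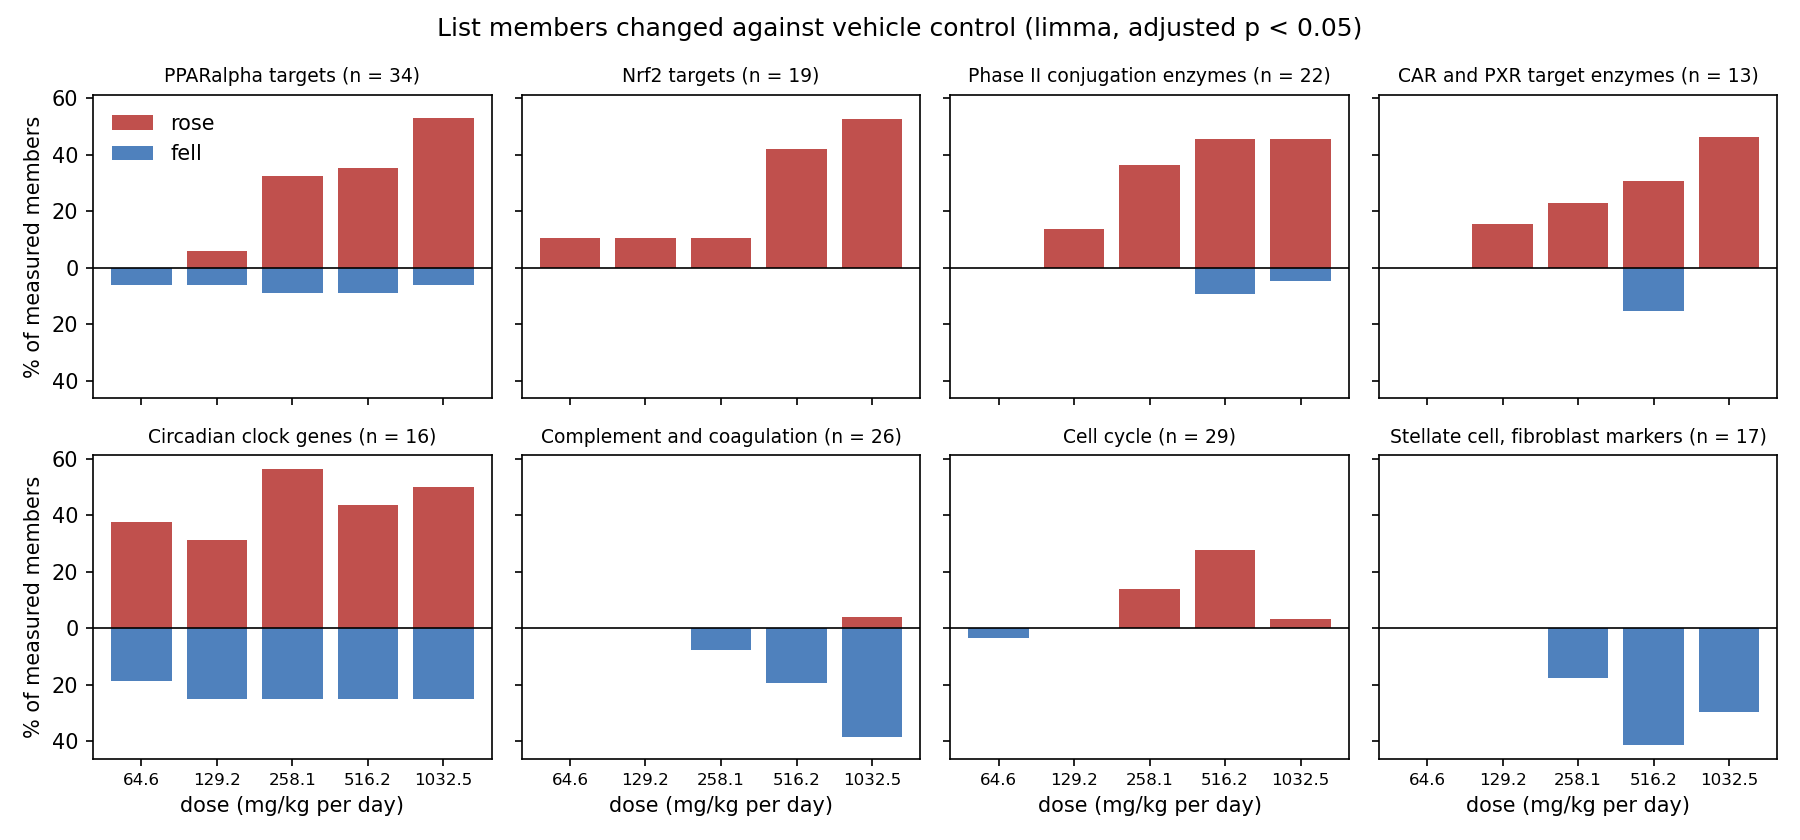
Percent of measured members of 8 gene lists that were higher (up) or lower (down) than in the vehicle arrays at each dose in mg/kg, limma adjusted p under 0.05, 3 treated against 6 vehicle arrays. At 1032.5 mg/kg 18 of 34 PPAR alpha targets and 10 of 19 Nrf2 targets were higher, while 10 of 26 complement and coagulation genes were lower.

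Liver secretory and amino acid genes fell more often than they rose at 1032.5 mg/kg. Of 26 complement and coagulation genes, 1 rose and 10 fell, or 1 and 14 adjusted over the list alone (camera adjusted p = 6.11e-06, and adjusted p = 0.185 with an estimated correlation). Mannose-binding lectin, Mbl2, was 1.69-fold lower (log2 change -0.76, SE 0.10, adjusted p = 8.96e-05) and heparin cofactor, Serpind1, 1.44-fold lower. Masp1 was 1.47-fold lower, but its next probe set gave a log2 change of 0.10 (adjusted p = 0.774). Of 21 acute phase genes, 4 fell and none rose, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0109, and adjusted p = 0.375 with an estimated correlation). Without replicate 3 of this dose A2m, Itih3 and Itih4 of these were lost (adjusted p = 0.0976, 0.170 and 0.242). Of 28 urea cycle and amino acid genes, 3 rose and 7 fell, or 6 and 12 adjusted over the list alone (camera adjusted p = 0.110), with Oat 4.32-fold lower (adjusted p = 3.16e-07) and the alanine aminotransferase gene Gpt 1.75-fold higher. Of 17 genes of glucose handling, 1 rose and 2 fell, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.468). These calls, Pck2, Igfbp1 and Pygl, were lost without replicate 1 (adjusted p = 0.0561 for Pck2) or replicate 2 (0.165 for Igfbp1 and 0.0587 for Pygl). Of 18 secreted and core hepatocyte markers, 2 fell, or 3 with 1 rise adjusted over the list alone (camera adjusted p = 0.0612). Of these calls, Apoc3 was lost without replicate 3 of this dose (adjusted p = 0.0624). Ahsg was lost whichever single vehicle or 1032.5 mg/kg array was left out (adjusted p from 0.0616 to 0.215), and with only the compared groups in the fit (0.134).

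Some markers of macrophages, stellate cells, lymphocytes, endothelium and red cells fell at 1032.5 mg/kg. Of 14 Kupffer cell and macrophage markers, 4 fell and none rose, or 11 and none adjusted over the list alone (camera adjusted p = 1.44e-06, and adjusted p = 0.291 with an estimated correlation), with lysozyme, Lyz2, 1.85-fold lower (adjusted p = 0.00229). Of 17 stellate cell and fibroblast markers, 5 fell, as many as adjusted over the list alone (camera adjusted p = 4.37e-05, and adjusted p = 0.326 with an estimated correlation), with Pdgfra 1.72-fold lower. The call of Col3a1 was lost without replicate 2 or 3 of this dose (adjusted p = 0.0852 and 0.135). Pdgfrb and Reln did not pass on their next probe sets (log2 change -0.08 and -0.55, adjusted p = 0.697 and 0.0709). Of 17 lymphocyte markers, 2 fell, or 3 adjusted over the list alone (camera adjusted p = 0.000693, and adjusted p = 0.291 with an estimated correlation), with the B cell gene Ms4a1 1.39-fold lower. Of 14 endothelial markers, 1 fell, or 5 adjusted over the list alone (camera adjusted p = 0.00738, and adjusted p = 0.488 with an estimated correlation). It was Stab1, a call lost without replicate 2 or 3 of this dose (adjusted p = 0.0879 and 0.124) and with only the compared groups (0.0611). Of 8 red cell markers, 3 fell, or 4 with 1 rise adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.389 with an estimated correlation). Hbb, a globin gene, was 4.03-fold lower (adjusted p = 0.00506), and without replicate 3 of this dose all 3 calls, Hbb, Alas2 and Hba-a3, were lost (adjusted p = 0.0567, 0.115 and 0.104). The same omission ended 3 of the 4 macrophage calls, Cd163, Adgre1 and Laptm5 (adjusted p = 0.0529, 0.211 and 0.153). Laptm5 was also lost without replicate 1 or 2 of this dose (adjusted p = 0.146 and 0.0744) or vehicle replicate 1, 2, 3, 4 or 6. Adgre1 was also lost without replicate 2 of this dose (adjusted p = 0.0979) or vehicle replicate 1, 2 or 3.

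Stress and cell cycle lists were also read at 1032.5 mg/kg. Of 23 genes of ER stress and ATF4, 6 rose and 1 fell, or 6 and 2 adjusted over the list alone, and the list did not shift (camera adjusted p = 0.247, with a median of -0.04 and a mean of 0.26). The amino acid response genes led the rises, with Asns 3.34-fold higher (adjusted p = 0.000950), Psat1 3.08-fold and Trib3 2.60-fold. Of 13 p53 targets, 2 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.218). Cdkn1a was 4.98-fold lower while Mdm2, which marks p53 for degradation, was 1.85-fold higher (adjusted p = 1.42e-05). Of 29 cell cycle genes, 1 rose and none fell, the same adjusted over the list alone, while the median was -0.22 (camera adjusted p = 0.0966). The rise was that of Kif11, whose next probe set did not pass (log2 change 0.12, adjusted p = 0.735). Of 16 clock genes, 8 were higher and 4 lower, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.00186, and adjusted p = 0.109 with an estimated correlation).

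The graded design was next tested as a slope over the dose steps, with all 21 arrays. A slope was called for 3251 probe sets (1821 rising, 1430 falling), and 1434 probe sets differed among the 6 groups by limma's moderated F. Among the 15 dosed arrays alone a slope was called for 708 probe sets (454 rising, 254 falling). Dose-graded genes there included Acot1 (adjusted p = 0.000106), Ces2c (0.63 per step, adjusted p = 2.41e-05), Gsta3 (0.61 per step, adjusted p = 1.82e-05) and Slc6a6 (-0.68 per step, adjusted p = 0.000128). Dbp gave 0.09 per step (SE 0.06, adjusted p = 0.538) and Nfil3 -0.01 per step (adjusted p = 0.968). Of 42 probe sets called at all 5 doses, each in the same direction throughout, 8 had a slope in that direction among the dosed arrays, and of the 1908 called at 1032.5 mg/kg 535 did. Of the gene lists, 3 sloped among the dosed arrays with an estimated correlation: Nrf2 targets (adjusted p = 0.00806) and PPAR alpha targets (adjusted p = 0.0364) upwards, and bile acid genes (adjusted p = 0.0361) downwards. On a scale of mg/kg in place of steps 1846 probe sets had a slope over all arrays.

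Neighbouring doses were also compared directly, 3 arrays against 3. No probe set passed limma's adjusted threshold in any of the 4 comparisons. At an unadjusted p under 0.05 there were 1546 probe sets between 129.2 and 64.6 mg/kg, 1567 between 258.1 and 129.2, 2140 between 516.2 and 258.1 and 2886 between 1032.5 and 516.2 mg/kg, and the smallest adjusted p-values were 0.423, 0.241, 0.452 and 0.0625. From 516.2 to 1032.5 mg/kg Acot1 differed by 1.43 on the log2 scale (adjusted p = 0.522), Ces2c by 0.75 (adjusted p = 0.393) and Cyp1a1 by 1.58 (adjusted p = 0.121). Across the whole dosed range, 1032.5 against 64.6 mg/kg, 458 probe sets differed (266 higher, 192 lower at the higher dose), a comparison added after the data had been seen. With limma's array weights the neighbouring counts were 206, 568, 0 and 10, and with only the groups compared in the fit 4 probe sets passed between 129.2 and 64.6 mg/kg and 0 in the other comparisons. Without replicate 2 of 516.2 mg/kg 86 probe sets passed between 1032.5 and 516.2 mg/kg and 1 between 516.2 and 258.1, without replicate 3 of 1032.5 mg/kg 8 passed in the former, and without replicate 3 of 258.1 mg/kg 1 passed between 258.1 and 129.2 mg/kg.

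The last comparison asked how alike the profiles of neighbouring doses were. Across 14217 genes, which are not independent replicates, fold changes correlated at r = 0.637 between 64.6 and 129.2 mg/kg, 0.725 between 129.2 and 258.1, 0.776 between 258.1 and 516.2 and 0.796 between 516.2 and 1032.5 mg/kg. Simulated unchanged groups that shared a simulated vehicle mean gave r of about 0.333, 0.333, 0.334 and 0.335. These values follow from the group sizes, since the noise was independent for each gene and array-wide differences were left out. With the vehicle arrays split 3 and 3 so that none was shared, the observed values were 0.391, 0.516, 0.627 and 0.675. The covariances were 0.0227, 0.0334, 0.0542 and 0.0701, beside simulated ones of 0.00627, 0.00624, 0.00627 and 0.00633. Of the probe sets called, 44 moved in the same direction at both 64.6 and 129.2 mg/kg, where independent lists would share 0.137, and 942 did at both 516.2 and 1032.5 mg/kg, where independent lists would share 58.8. Neither reference accounts for the shared controls and the real effects together.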

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

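Within the 6 vehicle arrays, 160 measures were screened for a single array far from the other 5, and 14 exceeded the 95% critical value of Dixon's ratio of gap to range, where chance gives about 8. Vehicle replicate 6 exceeded it for 6 of these. Its mean correlation with the rest of its group was 0.989 against 0.993 for the nearest array (ratio 0.900). Its mean log2 level was 7.82 against 7.74 for aryl hydrocarbon receptor targets (ratio 0.626), 9.99 against 9.37 for glucocorticoid-responsive genes (ratio 0.693) and 6.10 against 5.58 for neutrophil markers (ratio 0.887). In the same array the neutrophil gene S100a9 stood at 9.29 against 7.02 (ratio 0.696) and Rprm at 7.07 against 8.41 (ratio 0.721).

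Other vehicle arrays stood apart in single genes. Replicate 5 was high for the fetuin gene Ahsg, at 14.77 against 14.72 (ratio 0.811), and low for Laptm5, at 8.65 against 8.84 (ratio 0.730). Replicate 4 was high for Akr7a3, at 11.81 against 11.34 (ratio 0.768), and replicate 1 was low for Hbb, at 12.34 against 13.22 (ratio 0.637). Replicate 3 was low for the kinesin gene Kif11, at 5.16 against 5.66 (ratio 0.685), and for Masp1, at 10.56 against 10.86 (ratio 0.713). Replicate 2 was low for Per3, at 4.83 against 5.26 (ratio 0.688), and high for the endothelial gene Stab1, at 8.49 against 7.93 (ratio 0.800).

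The rise in counts from 258.1 mg/kg upwards was weighed against 3 technical explanations, each with its bounds set before its test was run, although the RNA integrity covariate and the slope among dosed arrays were chosen after the data had been seen. With the RNA integrity covariate 1828 probe sets changed at 1032.5 mg/kg in place of 1908, and without vehicle replicate 6 there were 2052. Neither explanation accounted for the count at that dose, the only one for which bounds were set. With the covariate 848 changed at 258.1 mg/kg in place of 731, and 1411 at 516.2 mg/kg in place of 1868. The 516.2 mg/kg group had the lowest mean 5' minus 3' difference (-2.30), so a part of RNA integrity in its count stays open. A vehicle group unlike all dosed groups, acting alone, would leave few slopes among the dosed arrays, where 708 were found. The test cannot exclude such a difference alongside a dose effect. Of the 1908 probe sets called at 1032.5 mg/kg, 1373 had no slope called among the dosed arrays. The dose, the biological alternative the design offers, was left standing by these tests, and so was a vehicle difference behind part of the count.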

How the results depend on the processing

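Of 113 named genes called at 1032.5 mg/kg, 71 stayed called in the same direction under every setting run for single genes (compared groups alone, cyclic loess, dim probe sets removed, block, covariate, next probe set and each array left out), and 33 were lost without some array. Masp1 turned to 0.10 on its next probe set. Cyclic loess, subtracted medians and removal of the dimmer probe sets moved no count beyond 1.5 times. Array signal over background was not analysed here. The number of arrays limits precision, and unless the setting shows it, the cause was not tested.

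With only the compared groups in the fit, and so fewer arrays for the spread, 474 probe sets changed at 258.1 mg/kg and 4 between 129.2 and 64.6 mg/kg. With 1 probe set per gene, or with an intensity trend and robust variance, 1 differed between 1032.5 and 516.2 mg/kg. Array weights gave 126, 2129, 1207 and 2884 at 64.6, 129.2, 258.1 and 1032.5 mg/kg, 4474 among the 6 groups, and 206, 568 and 10 between 129.2 and 64.6, 258.1 and 129.2, and 1032.5 and 516.2 mg/kg; replicate 2 of 129.2 mg/kg had a weight of 6.18. Requiring a fold of 1.5 as well, a stricter rule by construction, left 356, 630 and 841 at 258.1, 516.2 and 1032.5 mg/kg, 880 for the slope over the 5 steps and 854 among the groups. The slope on mg/kg gave 1846, and the slope in the 15 dosed arrays alone, chosen after the data were seen, 708. The RNA integrity covariate, also chosen then, gave 1 between 258.1 and 129.2 mg/kg.

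With an estimated correlation 0, 0, 0, 0 and 1 lists shifted, in place of 9, 13, 16, 14 and 14. By fry 4, 5, 12, 18 and 18 lists were called in order of dose. With split vehicle arrays, which removes the shared controls, the correlations were 0.391, 0.516, 0.627 and 0.675.

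The replicate number as a block gave 42 at 64.6 mg/kg, 47 at 129.2 and 5 between 258.1 and 129.2 mg/kg. The labels give no pairing, and 9 of 18 arrays correlated best with their own number, out of 3 numbers each. For deviations from the group means, the median r was 0.0054 over same-numbered pairs and -0.0069 over differently numbered pairs.

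Leaving out 1 array at a time, with fewer arrays by construction, gave 42 to 88 at 64.6 mg/kg, 34 to 104 at 129.2, 244 to 1048 at 258.1, 631 to 2499 at 516.2 and 1136 to 2052 at 1032.5 mg/kg. It gave 0 to 1 between 258.1 and 129.2 and between 516.2 and 258.1 mg/kg, and 0 to 86 between 1032.5 and 516.2 mg/kg.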

Other observations

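Further lists were read at 1032.5 mg/kg. Of 17 interferon response genes, 3 rose, or 6 with 1 fall adjusted over the list alone (camera adjusted p = 0.00470, and adjusted p = 0.529 with an estimated correlation), with Isg15, a ubiquitin-like modifier, at a log2 change of 0.82 (adjusted p = 0.0134). Without replicate 1 of this dose all 3 calls, Isg15, Oas1a and Usp18, were lost (adjusted p = 0.0973, 0.181 and 0.172), and those of Oas1a and Usp18 also without either other array of this dose or vehicle replicate 2, 4 or 5. Of 13 glucocorticoid-responsive genes, 3 rose and 2 fell, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.597, with a median of 0.21 and a mean of -0.18). The metallothionein gene Mt2A was 3.89-fold higher (SE 0.46, adjusted p = 0.0120) and the growth factor binding protein gene Igfbp1 4.36-fold lower (adjusted p = 0.0236). The call of Mt2A was lost without replicate 1 or 2 of this dose (adjusted p = 0.0643 and 0.0570) and with only the compared groups in the fit (0.0935). That of Igfbp1 was lost without replicate 2 or 3 (adjusted p = 0.165 and 0.0626) and with the RNA integrity covariate (0.0531). None of 10 heat shock genes passed, although 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.380), and the mitochondrial chaperone gene Hspd1 had a log2 change of 0.20 (adjusted p = 0.185).

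Zonation and sex-biased genes moved in part. Of 13 pericentral genes, 1 rose and 4 fell at 1032.5 mg/kg, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0497, and adjusted p = 0.284 with an estimated correlation), led by Oat and Cyp1a2. Of 13 periportal genes, 1 rose and 3 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0930), with the mitochondrial dehydrogenase gene Aldh1b1 2.08-fold lower. Of the falls, Cyp2f4 was lost without replicate 2 of 1032.5 mg/kg (adjusted p = 0.165). Igf1 was lost without replicate 2 or 3 of that dose (adjusted p = 0.0714 and 0.0615). Of 7 male-biased genes, 1 rose and 1 fell, or 2 and 1 adjusted over the list alone (camera adjusted p = 0.916), and Cyp2c11, the main male-specific form, was 1.89-fold lower (adjusted p = 0.00124), while the rise of Cyp3a18 was lost without any array of this dose (adjusted p = 0.0698, 0.122 and 0.193). Of 5 female-biased genes, 1 rose, the same adjusted over the list alone (camera adjusted p = 0.353), namely Cyp2c12 at 1.74-fold. Of 12 cholangiocyte markers, 1 rose, the same adjusted over the list alone (camera adjusted p = 0.727, with a median of -0.03 and a mean of 0.01), namely Epcam at 1.63-fold. None of 9 neutrophil markers passed, also adjusted over the list alone (camera adjusted p = 0.174), and S100a9 had a log2 change of -0.98 (adjusted p = 0.237).

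Of the tests below, those of the time of day and of the second component were chosen after the results they bear on were seen, and the RNA integrity covariate and the slope among the dosed arrays were added after the data had been seen. The clock genes were already shifted at the lowest dose. Of 12 clock genes called at 1032.5 mg/kg, 3 (Bmal1, Hlf and Npas2) had a slope in the direction of their shift among the dosed arrays. Nr1d1 had one against it (-0.16 per step, adjusted p = 0.0270). These slopes were adjusted over the 12 genes alone. Adjusted over all probe sets, only Npas2 kept a slope (adjusted p = 0.0125, and 0.104 for Bmal1 and 0.148 for Nr1d1). These values leave open whether vehicle livers were taken at another time of day. The labels give no hour, and such a difference would fall with the vehicle group. An action of the compound stays open as well. The same limit applies to Hsd17b2, Usp2, Cdkn1a, Lgalsl and Tubb2a, which were called at every dose without a slope called among the dosed arrays. Of 42 probe sets called at every dose 8 had a slope in their direction there, and the limit applies to the rest as well. The median share of the top-dose shift present at 64.6 mg/kg was 95.7% for the 12 clock genes, 41.2% for phase II enzymes and 12.5% for Nrf2 targets. It was 6.58% for PPAR alpha targets and 28.5% for 1260 other genes. These shares restate the clock pattern and test no explanation of it. RNA integrity did not account for the clock pattern, as 11 of the 12 were still called with the covariate and Clock was lost (adjusted p = 0.0893).

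The second principal component carried 13.5% of the variance. Centred within groups, it correlated with the 5' minus 3' difference at r = -0.630 (permutation p = 0.00256, 21 arrays), with a rank correlation of -0.600 (p = 0.00807) and r = -0.658 without the 2 arrays farthest in that difference. Without centring r was -0.623 over the 21 arrays (permutation p = 0.00261). The spread along this component is therefore consistent with a difference in RNA integrity between arrays, by r = -0.630. No biological explanation was tested.

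Other splits of the same arrays into groups of the same sizes tested whether chance could give the counts. For the probe sets changed against the vehicle it was unlikely at every dose, at the smallest share that 84 splits can reach. Only the real split, 1, gave as many: 77, 108, 731, 1868 and 1908, where the highest other splits gave 4, 4, 294, 427 and 4. The same held, with 1 of 100 orders, for the slope (3251, highest other 9), the slope among dosed arrays (708, highest other 123) and the moderated F (1434, highest other 7). For shifted lists chance could not be excluded at 64.6 mg/kg, with 9 lists and 24 of 84 splits as large (highest other 12), or at 516.2 mg/kg, with 14 lists and 8 of 84 (highest other 16). At 129.2 mg/kg only the real split, 1 of 84, gave as many as 13 lists (highest other 12). As large were 2 of 84 splits at 258.1 mg/kg, with 16 lists (highest other 16). At 1032.5 mg/kg, with 14 lists, 4 of 84 were (highest other 19). These shares were not adjusted over the doses. At 258.1 and 1032.5 mg/kg another split gave as many lists or more, so chance was not excluded there. Between neighbouring doses the real count was 0, which all 10 of 10 splits reach by construction, so these splits decide nothing. The highest others were 0, 2, 137 and 955. The last set replicates 1 and 3 of 516.2 mg/kg with replicate 1 of 1032.5 mg/kg against the other 3 arrays. This difference among samples crosses dose. The 5' minus 3' difference was -2.49, -2.83 and -1.96 on the arrays set together and -1.58, -1.37 and -1.28 on the others. The split that gave 137 set replicates 1 and 3 of 516.2 mg/kg with replicate 1 of 258.1 mg/kg. There the values were -2.49, -2.83 and -3.10 against -1.65, -1.35 and -1.58. Both splits thus divided the arrays fully by this measure of RNA integrity, whose part in these counts was not tested.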
